A study of Arabidopsis thaliana with 6 samples.

How the data were processed

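Leaf RNA of 3 wild-type and 3 sto2 mutant samples was compared on single-colour Affymetrix arrays. Per the labels' protocols, plants were grown in soil under 16 h light and 8 h dark at 22 and 18 °C without further treatment, total RNA was extracted with a Qiagen RNeasy kit, and an Affymetrix service provider did labelling, hybridisation and scanning. Groups were taken from the labels, which give each sample's genotype. Replicate numbers came from the sample titles.

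The deposited values were linear signal intensity values with 1 decimal, between 0 and 6616. The method that summarised probes into probe sets is not given in the sources used here. From the values themselves, every array had the same 2% trimmed mean of 100.009 while its quartiles differed, which is the mark of 1 scaling factor per array and no quantile normalization. Array medians differed by less than 0.1 on the log2 scale, so by the rule set beforehand no further normalization was applied. No scanner files were used here, so there were no detection calls. As a stand-in chosen after seeing the data, a reading was called above the controls when it exceeded the highest reading, on the same array, of 27 control probe sets for bacterial transcripts that read near 0. That highest reading ranged from 9.5 to 18.4, and between 23.0% and 34.0% of probe sets lay at or below it. Where a group lay at or below it on all its arrays, the fold is given as at least the ratio of the brighter group's mean to a floor. The floor takes, per array, the higher of that control reading and the probe set's own reading, and means were taken on the log2 scale.

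Of 22810 probe sets, 64 controls were left out and 22746 were tested. The gene table listed 13513 probe sets with 1 gene and 503 with several, and 8730 were unlisted; 13484 of those with 1 gene had a locus, giving 13333 loci. Names were checked against a RefSeq gene table of assembly TAIR10.1, which was used for names and for which genes neighbour each other. The build of the array design is not given in the sources used here, so no coordinates are given.

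Values were tested as log2(signal + 16) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided), with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. Fold changes on that scale understate the change of dim transcripts, so linear means are given beside them. The 2-fold count asked for a change of at least 1 on that scale as well. List medians include members that read no higher than the bacterial controls. Gene lists were tested with camera at a preset correlation of 0.01, using for each gene its probe set with the highest mean over the 6 arrays, and adjusted over the tested lists together with the plastid set. The lists were fixed before the data were examined; the minimum of 3 measured members was chosen afterwards, once it was clear how few members the table names. Plastid genes were taken by their sequence in the RefSeq table, because their locus tags there differ from the planned prefix, and mitochondrial transcripts were not analysed here. RNA quality ratios were compared by exact permutation.

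Genes were named by a rule fixed before the data were examined. It took, among probe sets with 1 gene and non-overlapping groups, the 12 largest changes past the threshold in each direction. Where fewer passed, it took all that passed and then those with the smallest p up to 8 in a direction, as values only. For each list it took up to 4 members that passed, or else up to 2 with the smallest p as values. Unnamed probe sets, given without their IDs, and a few further list members were picked after their values were seen.

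The procedure was tested on simulated data: with 200 of 22746 probe sets changed, it called 28.4% of those with a log2 change of 0.5, 82.1% at 1 and 98.5% at 2, with 3 false calls. All 200 were drawn from the brighter 50% of probe sets, so these rates do not cover dim ones. Noise was drawn independently for each probe set and array, so noise shared between probe sets was not simulated. Alternatives fixed beforehand were quantile normalization, median centring, leaving out the dimmest 30% or 50% of probe sets, an intensity trend with a robust prior, array weights, only probe sets with 1 gene, the replicate number as a block, pseudocounts of 1 and 64, and leaving out each array in turn. For lists, fry, an estimated correlation and the mean of a gene's probe sets were also planned.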

Results

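Transcript levels were measured on 6 single-colour Affymetrix arrays of Arabidopsis thaliana, each hybridised with biotin-labelled total RNA from expanding rosette leaves. Leaves 3 to 6 were taken from soil-grown plants that were 3 weeks old. Wild-type plants of the Col-0 accession and sto2 null mutants were each represented by 3 samples, which the design text describes as biological replicates. The comparison asks which transcripts differ in sto2 leaves, and the design text gives the search for possible downstream targets of the STO2 protein as its purpose. No label or gene table used here gives the locus of STO2, so the mutated gene was not examined as a check of the labels. Array medians lay between 37 and 38.5 signal units, and the highest signal on any array was 6616. The number of arrays limits the precision of every value below.

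The transcript with the smallest p-value was AT5G08520, a MYB-related transcription factor gene, whose signal fell from 251 ± 17.2 in wild type to 0.6 ± 0.1 in sto2 (mean ± SD, n = 3 arrays each). The sto2 readings, 0.5, 0.6 and 0.7, all lay at or below the highest bacterial control reading of their own array, so the decrease was at least 19.97-fold. On the log2(signal + 16) scale the change was -4.01 ± 0.08 (SE), with a limma adjusted p of 9.57e-06. AT5G08500, which encodes a transmembrane protein of the CLPTM1 family and lies close to AT5G08520 on chromosome 5, fell from 126 ± 15.1 to 54.7 ± 2.89 (adjusted p = 0.0257). The measured gene between them, AT5G08510, had signals of 35.7 ± 8.92 and 27.1 ± 3.96 and did not pass (adjusted p = 0.472). The reference gene table places 2 protein-coding genes between AT5G08500 and AT5G08520, and 1 of them is named on the array.

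In the other direction, the cytochrome P450 gene CYP71B22 (AT3G26200) rose from 70.1 ± 9.81 to 349 ± 28.9, a 4.98-fold increase (log2 change 2.09 ± 0.11, adjusted p = 0.00272). AT2G36885 rose 1.92-fold, from 247 ± 5.61 to 476 ± 37.4, and AT3G04000, which encodes a Rossmann-fold reductase, rose 2.201-fold, from 34 ± 1.35 to 74.8 ± 5.81. Their adjusted p-values were 0.0216 and 0.0215.

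Another 5 named genes fell. AT3G46370, a leucine-rich repeat receptor kinase gene, went from 23.1 ± 3.40 to 1.5 ± 0.17, at or below the bacterial controls on the 3 sto2 arrays, which bounds the decrease at 1.82-fold or more (adjusted p = 0.00859). AT1G73480, an alpha/beta hydrolase gene, fell from 315 ± 53.1 to 125 ± 5.34, and the expansin-like gene EXLB1 (AT4G17030) fell from 101 ± 13.8 to 43.7 ± 1.97. AT4G38690, which encodes a phospholipase C-like phosphodiesterase, fell from 117 ± 3.20 to 61.1 ± 6.29. These 3 genes shared an adjusted p of 0.0363. AT2G03470 fell from 159 ± 13.3 to 85 ± 5.67 (adjusted p = 0.0442).

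**Figure D1:**
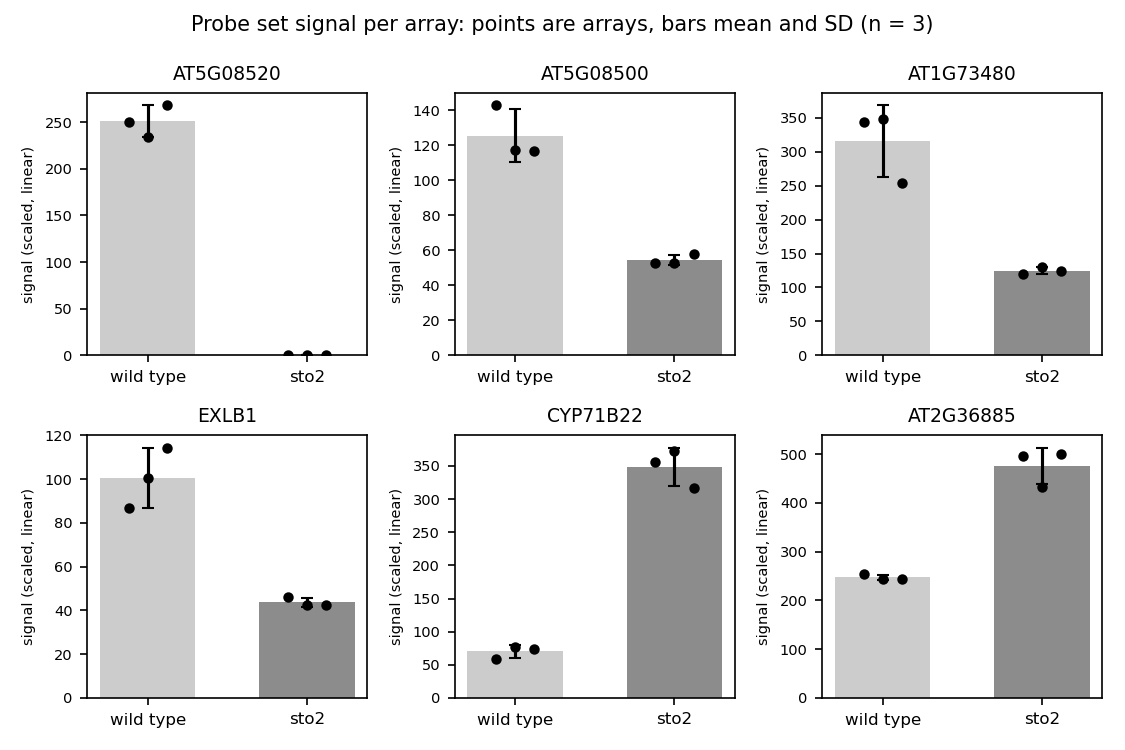
Probe set signal (scaled, linear) of 6 genes past the threshold on each array, with points for arrays and bars for the mean and SD of 3 wild-type or 3 sto2 arrays. In every panel the 3 sto2 arrays lie outside the range of the 3 wild-type arrays, as the naming rule required. The sto2 readings of AT5G08520 lie between 0.5 and 0.7.

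Over the whole array, 13 probe sets were higher and 16 were lower in sto2 among 22746 tested, and 16 of these 29 differed by at least 1 on the log2(signal + 16) scale, 8 in each direction. That scale understates folds of dim transcripts, so several of the other calls exceed 2-fold in linear signal, AT3G04000, AT5G08500 and EXLB1 among them. At an unadjusted p under 0.05 there were 3209 probe sets, 14.1% of those tested. The wild-type and sto2 values did not overlap in any of the 29, against 19.2% of all probe sets and 10% for chance with 3 against 3. Passing the threshold with 3 against 3 arrays all but requires separate groups, so this contrast is no further support for the calls. Of the 29 probe sets, 10 paired with 1 gene each and are those named above, 2 paired with several genes, and 17 were not listed in the gene table and stay unnamed here. One unnamed probe set fell from 1109 ± 192 to 23.8 ± 5.18 (log2 change -4.81 ± 0.16, adjusted p = 1.70e-04). It still read above the bacterial controls on all 3 sto2 arrays. Of the 13 higher probe sets, 10 had no single gene. Among all 13 the largest log2 change belonged to one that paired with several genes, from 13.4 ± 2.78 to 173 ± 33.3 (log2 change 2.68 ± 0.15, adjusted p = 0.00272), with 2 of the 3 wild-type arrays above the bacterial controls. Unlisted probe sets among those that rose went from 45.9 ± 6.13 to 255 ± 48.6, from 112 ± 13.3 to 440 ± 64.4 and from 75.8 ± 2.74 to 281 ± 36.4.

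Counts of calls fell below 29 whichever array was left out, in fits with 1 array fewer, and varied with the array. Without wild type replicates 1, 2 or 3 in turn, 22, 7 and 11 probe sets were called, and without sto2 replicates 1, 2 or 3, 8, 7 and 5. AT5G08520 and CYP71B22 passed in each of these 6 fits, while AT2G36885, AT3G04000, AT4G38690 and AT2G03470 passed in none of them. The log2 changes of these latter genes moved little. They ran from 0.86 to 0.96 for AT2G36885 and from 0.81 to 0.90 for AT3G04000. For AT4G38690 they ran from -0.85 to -0.73, and for AT2G03470 from -0.84 to -0.73.

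The next named genes by p-value did not pass the threshold. AT3G56360 read 76.3 ± 27.8 in wild type and 320 ± 57.7 in sto2 (log2 difference 1.89 ± 0.22, adjusted p = 0.0575), and the aspartyl protease gene AT1G62290 read 85.9 ± 15.9 and 257 ± 51.8 (1.42 ± 0.17, adjusted p = 0.0610). AT3G52390 (adjusted p = 0.0501), AT1G09740 and ATMDAR2, a monodehydroascorbate reductase gene (both adjusted p = 0.0610), had log2 differences of 0.60, 0.64 and 0.52. For AT3G01690 the log2 difference was -0.58 (adjusted p = 0.0575).

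**Figure D2:**
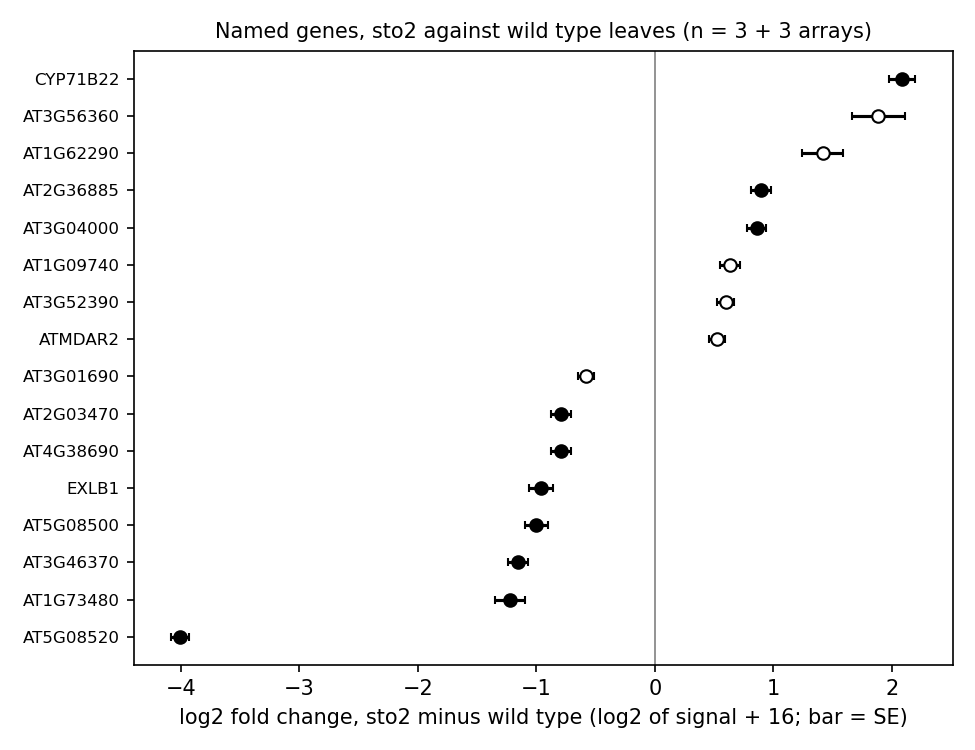
Log2 fold change, sto2 minus wild type, of log2(signal + 16) for the 16 named genes, with the standard error as bars (3 arrays per group). Filled points passed an adjusted p of 0.05 and open points did not; the values run from -4.01 for AT5G08520 to 2.09 for CYP71B22.

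Gene lists fixed beforehand held 594 members in 36 lists, but only 77 members could be matched to a named probe set. These 77 are called measured here, and none of them passed over all probe sets. Other members may be among the unlisted probe sets, which include 17 of the 29 calls. The 12 lists with at least 3 measured members and the plastid transcripts were tested with camera, and 0 passed an adjusted p of 0.05, against 3 at an unadjusted p under 0.05. With fry, and with camera at an estimated correlation, the number was also 0.

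Cold-regulated genes came nearest. All 5 measured members had lower mean values in sto2, with a median log2 difference of -0.48 (adjusted p = 0.0573, and adjusted p = 0.576 with an estimated correlation). For COR15A the difference was only -0.01 ± 0.38. It read 296, 834.3 and 321.2 on wild-type arrays 1, 2 and 3, against 363.8, 527.5 and 404.7 in sto2. Its lower mean in sto2 thus came from wild type replicate 2. COR47, a dehydrin gene, read 1152 ± 396 in wild type and 559 ± 28.2 in sto2. COR15B, which encodes a chloroplast cold-response protein, read 850 ± 52.1 and 557 ± 80.5. These 2 members passed when adjusted over the list alone (adjusted p = 0.0119 and 0.00715), and neither passed over all probe sets (adjusted p = 0.163 and 0.115). Without wild type replicate 3 the list passed (adjusted p = 0.00788), as it did without sto2 replicate 2 (adjusted p = 0.0447). It did not pass without wild type replicates 1 or 2, or without sto2 replicates 1 or 3. Over its 19 alternatives the adjusted p ran from 0.00788 to 0.576. The median was -0.19 without wild type replicate 2. Among the wild-type arrays, replicate 2 read highest for COR15A, COR15B, COR47 and XERO2, and replicate 1 did for ZAT10.

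Among the hormone lists, the 3 measured jasmonate genes had a median log2 difference of -0.60 (adjusted p = 0.0942; adjusted p = 0.576 with an estimated correlation). The median was -0.26 without wild type replicate 1, -0.37 without sto2 replicate 3 and -0.91 without sto2 replicate 1. The plant defensin gene PDF1.2 read 69.1 ± 28.2 and 27.6 ± 12.1 in wild type and sto2 and passed only when adjusted over the list alone (adjusted p = 0.0388). Wild type replicate 1 read highest for PDF1.2, at 101.5 against 56.2 and 49.7, and for PDF1.2b, at 138.4 against 53.7 and 65.6. THI2.1, a thionin gene, had a log2 difference of -0.32 ± 0.14 and read above the bacterial controls on 3 of the 6 arrays. The 5 measured auxin genes had a median of -0.24 (adjusted p = 0.238), which was -0.60 with the dimmest 30% or 50% of probe sets left out. Both filters dropped GH3.1, which read 3.83 and 2.3 in wild type and sto2, and left the values of the other auxin genes unchanged. Of these genes IAA29, an auxin-response repressor gene, read 354 ± 194 and 159 ± 72.5. The wide wild-type spread of IAA29 came from replicate 1, which read 578 against 242.5 and 241.5. YUC2, an auxin synthesis gene, had a log2 difference of -0.24 ± 0.14. The 3 gibberellin receptor genes had a median of -0.19 (adjusted p = 0.3002), with GID1B at -0.31 ± 0.11 and GID1A at -0.19 ± 0.08. The 2 measured cytokinin genes were too few for a list test. These were the response regulators ARR15, at 95.1 ± 14.3 and 58.0 ± 15.71, and ARR16, at 315 ± 96.2 and 181 ± 31.1. Both passed only when adjusted over the list alone (adjusted p = 0.0187 and 0.0203). EIN3, a transcription factor of ethylene signalling and the only measured member of its list, read 465 ± 43.6 and 373 ± 10.5 (adjusted p = 0.214 over all probe sets).

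Photosynthesis genes were read at high signal, and none of their tested lists passed. The 4 nuclear photosystem genes had a median log2 difference of -0.03 (adjusted p = 0.775), with PSAN at -0.13 ± 0.08 and PSBY at -0.05 ± 0.08. Their median was -0.0120 and -0.0523 without wild type replicates 2 and 3, and -0.0125 and -0.0661 without sto2 replicates 2 and 3. The 3 Calvin cycle genes had a median of 0.01 (adjusted p = 0.886), with the kinase PRK at 0.13 ± 0.10 and rubisco activase, RCA, at -0.10 ± 0.08. Their median turned to -0.0207 without wild type replicate 3 and to -0.0109 without sto2 replicate 2, and was 0.0409 and 0.0294 without wild type replicate 1 and sto2 replicate 3. The light-harvesting genes LHCB4.1 and LHCB4.2, too few for a list test, had differences of 0.06 and -0.11. In chlorophyll synthesis the 5 measured genes had a median of -0.08 (adjusted p = 0.775), which was -0.0222 without wild type replicate 1 and -0.12 without wild type replicate 2. CHLI2, a magnesium chelatase subunit gene, had a difference of 0.28 ± 0.07 and was the 1 member to pass when adjusted over the list alone, and PORB, a protochlorophyllide reductase gene, had -0.33 ± 0.11. The 4 flavonoid and anthocyanin genes had a median of -0.16 (adjusted p = 0.112; adjusted p = 0.576 with an estimated correlation). With a pseudocount of 1 the median was -0.42 and the list passed (adjusted p = 0.0461), the only 1 of its 17 alternatives to pass. Of these, UGT79B1 and DFR read only 17.9 ± 0.71 and 15.2 ± 4.54 in wild type, close to the bacterial controls. In sto2, DFR exceeded the controls on 0 arrays. UGT75C1 read 2.0 ± 0.61 in wild type and 1.17 ± 0.32 in sto2, at or below the controls on every array. Only UGT78D2, at 41.4 ± 5.02 in wild type, exceeded them on every array.

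Cell wall loosening genes had differences of both signs: 5 of the 7 measured expansin and xyloglucan endotransglucosylase genes had lower means in sto2 (median -0.30, adjusted p = 0.493). The median was -0.11 without wild type replicate 1, -0.10 without sto2 replicate 1 and -0.15 with a pseudocount of 64. Without the dimmest 50% of probe sets it turned to 0.10. That filter dropped XTH18, XTH19 and XTH33, at -0.73, -0.53 and -0.30, and left the values of the other members unchanged. EXPA15 read 70.6 ± 4.96 and 97.5 ± 8.34, and XTH18 read 24.9 ± 4.19 and 9.4 ± 7.81. Each passed only when adjusted over the list alone (adjusted p = 0.0232 and 0.0409). The 4 heat shock genes had a median of -0.04 (adjusted p = 0.886), with HSP15.7 at -0.22. The median was -0.0110, -0.0237 and -0.0819 without wild type replicates 1, 2 and 3 in turn, and -0.0170 without sto2 replicate 1. HSP17.6C read 9.87 and 12.4 and exceeded the bacterial controls on 1 of the 6 arrays.

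Markers of leaf cell types did not pass where their lists were tested. The 3 trichome genes had a median of -0.24 (adjusted p = 0.344), with TBR at -0.26 ± 0.07 and SIM at -0.24 ± 0.13; TBR passed only when adjusted over the list alone. Without sto2 replicate 3 the median was -0.14. The 3 stomatal lineage genes had a median of -0.0032 and a mean of 0.05, and the test leaned up (adjusted p = 0.775). MUTE, at 3.63 and 6.47 in wild type and sto2, and SPCH, at 6.67 and 5.77, each exceeded the bacterial controls on only 1 of the 6 arrays, so the list median rests partly on readings at background. FAMA, the other member, read 67.3 in wild type and had a log2 difference of -0.0032. The sucrose exporter SWEET11, a phloem marker, had a difference of 0.24 ± 0.18. Markers of the shoot apex, CLV3 and UFO, read under 5 signal units in wild type, and the root markers PYK10 and EXP7 read 11.8 and 14.7. CLV3 and UFO exceeded the bacterial controls on 0 of the 6 arrays, and PYK10 and EXP7 on 1 each.

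Lists with 1 or 2 measured members gave these values, none past the threshold over all probe sets. BCAT4, an enzyme gene of aliphatic glucosinolate synthesis, read 361 ± 269 and 905 ± 100 (adjusted p = 0.251; adjusted p = 0.0358 over the list alone), with wild-type arrays at 128.8, 655.1 and 298.5. UGT74C1 of the same list and UGT74B1 of the indolic list had log2 differences of 0.33 ± 0.26 and 0.27 ± 0.20. DPE1, for starch, had 0.16 ± 0.07, and GI, for the clock, -0.18 ± 0.11. HYH, for light signalling, GSTU25, for oxidative stress, and the iron regulator BHLH101 exceeded the bacterial controls on 0 of the 6 arrays. The defence genes WRKY22, WRKY53, SAG101 and GRX480 had differences of -0.42, -0.19, 0.14 and 0.03. The differences of the copper chaperone gene CCS and of the iron regulator PYE were 0.16 and 0.23. The senescence genes SAG29 and WRKY6 read 13.5 and 16.3 in wild type and exceeded the controls on only some arrays, and the division kinases AUR1 and AUR2 had -0.12 and 0.03. For 7 lists no member could be matched to a named probe set. These were abscisic acid and dehydration, salt and ion transport, brassinosteroid, phosphate starvation, epidermis and cuticle, xylem and secondary wall, and flower and flowering time. Their genes may be among the 8730 unlisted probe sets, so nothing is said here about their levels.

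Plastid-encoded transcripts did not pass as a set. Over 69 measured genes the median log2 difference was 0.01 and the mean 0.02, while the test leaned down (adjusted p = 0.775). The photosystem II gene psbJ read 1593 ± 72.2 in wild type and 1048 ± 79.1 in sto2 (adjusted p = 0.0732), and passed when adjusted over the list alone (adjusted p = 0.0165). For ccsA the difference was -0.48 ± 0.14. Without wild type replicate 2 the set's median was -0.14, with a camera adjusted p of 1.31e-04 at the preset correlation of 0.01. The correlation estimated for the set over all 6 arrays was 0.41, far above the preset value, so 1.31e-04 cannot be taken at face value. Over all 6 arrays camera with an estimated correlation gave an adjusted p of 0.919. An estimated correlation was not used without wild type replicate 2, so whether the set would pass there was not tested. Over its 19 alternatives the adjusted p ran up to 0.946.

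RNA quality was read from the 3' over 5' signal ratios of control transcripts. For the older actin probe sets the log2 ratio was 2.57 ± 0.06 in wild type and 2.05 ± 0.25 in sto2, a difference of -0.52 (exact permutation test, 2-sided, p = 0.1, the smallest that 3 against 3 allows; adjusted p = 0.6 over 6 ratios). The other 5 ratios, for GAPDH, ubiquitin and a second set of actin probes, differed by -0.08 to 0.05. Averaged over the 6 ratios, wild type stood at 0.80 ± 0.03 and sto2 at 0.71 ± 0.04 (exact permutation p = 0.1).

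Between arrays, log2 signals correlated at 0.981 to 0.988 within wild type, 0.989 to 0.991 within sto2, and 0.978 to 0.988 between the groups, over probe sets. The first principal component took 36.7% of the variance and separated the groups. The second took 26.3% and set wild type replicate 1 apart, at 29.02 against -12.3 to 5.66 for the other arrays. Wild type replicate 2 lay furthest out on the first component, at 24.7. It also held the lowest correlation of any pair, 0.978 with sto2 replicate 2.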

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

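All alternatives below were fixed before the data were examined. The 29 calls kept their direction where tested, as separate groups nearly force, and AT5G08520 passed the threshold in 16 of 16. CYP71B22 passed in 15 of 16, and of the other 8 named genes past the threshold each passed in 6 to 9, AT3G46370 out of 14. Except where stated, the cause of the shifts was not tested.

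Numbers of probe sets higher and lower were 21 and 19 with median centring, 67 and 80 without the dimmest 30%, 117 and 116 without the dimmest 50%, 36 and 36 with an intensity trend and robust prior, and 37 and 33 with array weights. They were 45 and 38 with a pseudocount of 64, and 11 and 6 with a pseudocount of 1, where only 11 of the 17 calls were among the 29. With only the 13484 probe sets of 1 gene they were 3 and 3. All 10 named calls were tested there and 6 were called again, while AT1G73480, EXLB1 and AT4G38690 (adjusted p = 0.0612 each) and AT2G03470 (adjusted p = 0.0709) no longer passed. Of the 29, 27 were called again without the dimmest 30%, where 27 were tested, and 22 without the dimmest 50%, where 22 were tested. At 2-fold or more on the log2(signal + pseudocount) scale the count was 32 under both dim filters, 3 with only probe sets of 1 gene and 9 with a pseudocount of 64. Leaving out 1 array at a time gave 3 to 14 higher, 2 to 8 lower and 5 to 19 at 2-fold, with fewer arrays in each fit. Without wild type replicate 1, 15 of the 22 calls were among the 29.

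Deviations of same-numbered arrays from their group means correlated at -0.23, -0.14 and 0.07 over probe sets. No wild-type array matched its own number best, but 3 numbers are too few to exclude pairing. With the replicate block 0 were higher and 2 lower, 2 of them at 2-fold, and 2 lists passed, cold-regulated and jasmonate genes (adjusted p = 0.0316 and 0.0162).

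The number of lists past the threshold was 1 with quantile normalization, median centring, either dim filter and only probe sets of 1 gene, 2 with a pseudocount of 1, and 0 to 1 when arrays were left out. Cold-regulated genes passed in 9 of 19 alternatives, jasmonate in 1 of 17 and flavonoid genes in 1 of 17; alternatives that left fewer than 3 members gave no value. Medians of 4 lists and of the plastid set changed sign in some alternatives, and of these only the plastid set passed in 1. Several list medians moved by over 1.5 times with the pseudocount. At 64 they were -0.15 for auxin, -0.15 for expansins and related genes, -0.07 for flavonoid genes, -0.37 for jasmonate and -0.0133 for heat shock, and at 1 heat shock stood at -0.18. Heat shock was also at -0.0218 with quantile normalization and -0.0182 with array weights, and photosystem genes at -0.0189 with array weights. Calvin cycle genes were at 0.0592, 0.0159 and 0.0222 with quantile normalization, centring and array weights. The stomatal lineage turned to 0.0023 with quantile normalization, 0.0022 with centring, 0.0665 with array weights and 0.0815 with a pseudocount of 1. Without 1 array it ranged from -0.11 to 0.23, with 0.23, 0.09, 0.07, 0.06 and 0.05 as the positive values. Calvin cycle genes turned to -0.0207 and -0.0109 without wild type replicate 3 or sto2 replicate 2, with 0.0409 as the highest without 1 array, expansins and related genes to 0.10 without the dimmest 50%, and photosystem genes to 0.0249 with quantile normalization. The plastid median turned to -0.0174 with array weights, changed sign without sto2 replicates 1 or 3 (-0.0123 and -0.0100), and to -0.14 without wild type replicate 2, where alone it passed (adjusted p = 1.31e-04), and was at most 0.0836 without 1 array. RNA quality moved by less than its spread, from -0.11 to -0.07. On these arrays 23.0% to 34.0% of probe sets read no higher than the bacterial controls, which limits what can be said of dim transcripts.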

Other observations

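In the tests below, only that of dim probe sets in wild type replicate 1 was chosen before its result was seen. The others, and the gene families, were chosen after, and the brighter-half count was planned, though the genes named from it were picked afterwards.

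With the dimmer 50% of probe sets left out, limma called 233 of 11373 probe sets, and 105 of them paired with 1 gene, 47 higher and 58 lower in sto2. In this smaller set AT5G55450 rose from 35.6 ± 6.56 to 260 ± 151 (adjusted p = 0.0226), AT3G56360 from 76.3 ± 27.8 to 320 ± 57.7 (adjusted p = 0.00843) and AT1G62290 from 85.9 ± 15.9 to 257 ± 51.8 (adjusted p = 0.00993). AT1G66100, a thionin family gene, fell from 593 ± 135 to 180 ± 39.1 (adjusted p = 0.0102). Further genes that fell were AT1G62510, from 233 ± 19.4 to 95.8 ± 27.1, AT3G49160, from 84.3 ± 10.8 to 32.4 ± 9.17, and EXLA1, an expansin-like gene, from 156 ± 11.9 to 99.6 ± 0.92. COR15B and psbJ also passed there (adjusted p = 0.0437 and 0.0226). None of these 9 genes passed over all 22746 probe sets.

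Of 30 gene families with at least 8 genes sharing the letters of their symbols, 0 passed with camera. The cytochrome P450 family, with 26 genes, had the smallest p (adjusted p = 0.773, median log2 difference 0.06), and CYP71B22 was its 1 member called.

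For the 29 calls, the RNA quality ratios argue against degradation differing between the groups in the way the actin ratio did. The mean of the 4 GAPDH and ubiquitin ratios differed by 0.016 ± 0.043 (SE), against -0.52 for the older actin probe sets. A degradation difference particular to some transcripts stays open, as does the genotype itself. The real split of the arrays was 1 of 10 with 29 or more calls, and the highest of the others called 1; 10 splits are too few for a share under 0.05.

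For the joint fall of AT5G08520 and AT5G08500, of the 39 other named genes within 20 on either side, 9 (23.1%, exact binomial 95% interval 11.1 to 39.3) had an unadjusted p under 0.05, against 14.1% of all probe sets, and 0 were called. This argues only against a segment of that width in which at least 50% of genes differ; a shorter one around both genes stays open, with AT5G08510 between them at -0.25 ± 0.14. In sto2 the AT5G08520 probe set read 0.5, 0.6 and 0.7 while the AT5G08500 probe set still read 53, 53 and 58. This argues against the AT5G08520 probe set reading the AT5G08500 transcript. Whether the AT5G08500 probe set reads the AT5G08520 transcript stays open, since no probe sequences were used here. The AT5G08500 probe set lost 71.0 units, 28.3% of what the AT5G08520 probe set lost. AT5G08520 may be the mutated locus, but 4 called probe sets (AT5G08520, AT3G46370 and 2 unnamed ones) went from above the bacterial controls on 3 wild-type arrays to at or below them on 3 sto2 arrays. AT5G08520 started at 251 and fell at least 19.97-fold, the others started at 23.1, 39 and 49 with bounds of 1.82, 3.09 and 3.77 that their lower signals cap, and a further unnamed probe set fell 46.5-fold from 1109 to 23.8 while staying above the controls, so the locus, like regulation by STO2, stays open.

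Wild type replicate 1 stood apart from the other arrays on the second principal component. On it GH3.3, an auxin-conjugating enzyme gene, read 288 against at most 75.6 elsewhere. IAA29 read 578 against at most 242.5, and psbK read 3017 against at most 1379. These genes were picked from those with the largest gaps to the other arrays, and no other array was ranked this way. They illustrate the gap and are no support for it. Noise of dim probe sets is argued against as the cause. In the brighter probe sets the variance of replicate 1's deviations was 1.77 times that of the other wild-type arrays (bootstrap 95% interval 1.71 to 1.83). This lay above the 1.2 set beforehand. The bootstrap resampled probe sets, so the interval does not measure how much arrays vary. RNA degradation in that sample stays open, since its ratio was the highest of the 3 wild-type arrays for 3 of 6 control pairs and the lowest for 3. No biological explanation was tested.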
